A study of Homo sapiens and Caenorhabditis elegans with 33 samples.

How the data were processed

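Small RNA sequencing was used on 15 libraries of day 1 adult C. elegans and 18 libraries of RKO cells, in groups read from the sample labels. The worm groups hold 3 libraries each. They are a strain with degron-tagged Dicer and no TIR1 (tag control), ubiquitous and germline depletion of Dicer, a TIR1-only strain, and ubiquitous depletion of RPC-1, all on 4 mM auxin for 24 h from L4 at 20 °C. The RKO groups are wild type, Dicer knockout and DGCR8 knockout (4 libraries each, 4 days of doxycycline), and DMSO or a Pol III inhibitor for 24 h (3 each). The genotype given for RPC-1 depletion replicate 3 names no RPC-1 degron allele, unlike its title, and the library was grouped by its title.

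For the worms the authors deposited estimated counts per mature miRNA arm and per spike-in RNA, which were not scaled. Per the submitters' processing notes cutadapt 4.4, Bowtie2 2.5.1, SAMtools 1.19, HTSeq 2.0.4 and DESeq2 were used, with no role or order given. All values are multiples of 0.5, with 148 values that are not whole among the 4290, and were rounded to whole counts before testing. The table holds 276 miRNA rows and 10 spike-in rows. For RKO cells the authors deposited a signal, a read count per mature miRNA divided by 1 factor per library, as the values themselves show. In each library all values (100%) were whole multiples of 1 step within 0.060, so whole reads could be recovered. The planned test assumed counts in both tables, so limma replaced edgeR for RKO. Per the submitters' processing notes cutadapt 5.0, UMI-tools 11.5, Bowtie2 2.5.3, SAMtools 1.21, HTSeq 2.04 and DESeq2 were used with GRCh38. Per the labels' protocols spike-in RNAs were mixed with RKO RNA too, but the RKO table holds no spike-in rows, and whether its factors rest on them is not stated.

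Worm libraries held 10125148 to 13538301 miRNA counts in the tag control, 3799989 to 5986773 after ubiquitous and 9139583 to 10476679 after germline Dicer depletion. In the TIR1-only control they held 10501487 to 13002050, and after RPC-1 depletion 8549783 to 15768105. Spike-in counts per library were 1879971 to 5819039. RKO libraries held 4773528 to 16742031 recovered reads in wild type, 5261714 to 9277745 in the Dicer knockout and 2341127 to 6140826 in the DGCR8 knockout. With DMSO they held 4546978 to 10731401 and with the inhibitor 6453779 to 12422964. On the deposited scale 1 read is worth most in the replicate 2 libraries of wild type (4.78), DGCR8 knockout (4.24), DMSO (2.73) and Dicer knockout (2.17). At these depths the count of an abundant miRNA is precise, and the spread between replicates sets the SE, while miRNAs with few counts are limited by counting. No 2 libraries of a group held the same counts (smallest chi-squared per degree of freedom 150.3 in worm and 45.6 in RKO).

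The rule for scaling was fixed before the data were examined, as were the tests (except limma for RKO), the lists and the rule for named miRNAs. Spike-in totals serve as library sizes where spike-in rows exist with at least 1000 counts in each library, and TMM where they do not. In the worm table spike-ins varied across libraries by a median SD of 0.12 after scaling (log2, largest 0.18). Worm miRNAs passing filterByExpr (229) were tested with edgeR 4.0.16 (quasi-likelihood, robust) on all 15 libraries in 1 fit, without a replicate block. RKO miRNAs passing filterByExpr (639) were tested with limma 3.58.1 (trend, robust) on log2 of TMM-scaled recovered reads plus 5, with all 18 libraries in 1 fit. A further 906 of 2652 RKO rows held no read. Called means a Benjamini-Hochberg adjusted p under 0.05. TMM centres the average miRNA, so a fall shared by most RKO miRNAs cannot show on that scale. Most RKO results are therefore also given on the deposited scale, on which many calls were not kept. RKO values on the deposited scale, and results of edgeR, DESeq2, total count and the block, had been seen before the fixed rule settled the TMM scale.

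Fixed lists of the mir-1829, mir-35, mir-51, let-7 and bantam families, somatic miRNAs and mirtrons were used in worms. In RKO cells they were the let-7, miR-15/16 and miR-200 families, the miR-17-92 clusters, mirtrons, capped, snoRNA-derived and tRNA-derived miRNAs, the chromosome 19 cluster, the Dicer-independent miR-451a and miRNAs of other tissues. Lists of at least 3 tested miRNAs were tested as sets with camera (limma, correlation preset to 0.01, and once estimated), with p-values adjusted over the lists. Calls were also adjusted over each list alone. Hairpin GC content and host genes came from the GENCODE v29 annotation of GRCh38. The named miRNAs are the mir-1829 rows in worm comparisons, up to 10 of the largest falls and 10 of the largest rises whose groups do not overlap at a mean count of at least 50, the 5 most abundant in the control, up to 4 abundant members per list, and the members of the intersections. Some of these are summarised in place of being named. Sums of deposited values were compared by exact permutation of the group labels.

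Replicate numbers occur in both groups of each comparison, and the labels do not say that a number marks a shared culture or day. The correlation of same-numbered libraries' deviations from their group means exceeded 0.1 for each pair only between the germline Dicer and tag control libraries (0.49 to 0.64), so the pairing there comes from the data. With the replicates paired, 44 miRNAs were lower and 1 higher in that comparison. Alternatives were TMM, DESeq2 1.42.0 size factors, total count and DESeq2 size factors on the spike-ins as scales, the DESeq2 Wald test, no filter, only the compared groups, a replicate block, and leaving out each library. Further ones were the deposited factors, a mean deposited value of at least 10 or 50, pseudocounts of 1 and 20, edgeR on recovered reads, and leaving out the 4 libraries in which 1 read is worth most or the third library of both RPC-1 groups. The code was tested on simulated data. Of 9 miRNAs lowered 4-fold among 227 with worm depth and spread 6 were called, of 10 lowered 2-fold 2, of 10 raised 2-fold 2 and of 10 raised 4-fold 9, with 2 false calls among 188. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. Raw reads were not used here, and the worm and RKO tables were never tested together.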

Results

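Small RNA was measured in 15 libraries of adult C. elegans and in 18 libraries of RKO colon carcinoma cells. In the worms an auxin degron removed Dicer, the RNase III enzyme that cuts precursor hairpins into mature miRNAs, or RPC-1, the large subunit of RNA polymerase III (Pol III). The small RNA tables hold no mRNA, so Dicer, DGCR8 and RPC-1 themselves were not analysed here and the removal of each target was not checked. Per spike-in count, the worm libraries held 4.29 ± 0.283 miRNA counts in the tag control, 0.896 ± 0.216 after ubiquitous and 3.07 ± 0.502 after germline Dicer depletion (mean ± SD, n = 3 each). In the RPC-1 experiment it was 4.1 ± 1.65 in the TIR1-only control and 3.79 ± 1.54 after RPC-1 depletion. There replicate 3 stood above the other replicates in both groups, at 6.0 in the control and 5.57 after depletion. Whether the replicates are separate cultures is not stated, so the p-values measure the spread between these samples. Worm levels are counts per 1000000 spike-in counts (mean ± SD), and changes are log2 fold changes ± SE.

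Ubiquitous Dicer depletion lowered most worm miRNAs. The miRNA mir-71_5p, linked to lifespan, had a level of 372612 ± 21753 in the tag control and 17219.5 ± 2925 after depletion (-4.44 ± 0.42, edgeR adjusted p = 6.8e-08). A larger fall, that of mir-235_3p of the miR-92 family, was from 10149 ± 716 to 354 ± 40.1 (-4.84 ± 0.32, edgeR adjusted p = 3.5e-10). The developmental timing miRNAs let-7_5p (-1.39 ± 0.41, edgeR adjusted p = 0.00452) and lin-4_5p (-0.89 ± 0.31, edgeR adjusted p = 0.0136) fell less. Both lay above the tag control when the scale was set by the miRNAs themselves: let-7_5p at 0.33 under TMM, 0.41 under DESeq2 size factors and 0.91 under total count. For lin-4_5p these values were 0.84, 0.91 and 1.42.

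All 6 rows of the mir-1829 family, whose need for Pol III the series addresses, fell. The arm mir-1829b_5p went from 55.3 ± 2.8 to 7.0 ± 0.369 (-2.98 ± 0.39, edgeR adjusted p = 2.7e-06), and mir-1829c_5p from 154 ± 18 to 21.4 ± 1.78 (-2.85 ± 0.42, edgeR adjusted p = 9.5e-06). Falls were also called for mir-1829a_3p* (-2.26 ± 0.38, edgeR adjusted p = 3.5e-05) and mir-1829a_5p (-1.35 ± 0.42, edgeR adjusted p = 0.00642). The last 2 arms, mir-1829c_3p* (-1.49 ± 0.51, edgeR adjusted p = 0.0124) and mir-1829b_3p* (-1.48 ± 0.53, edgeR adjusted p = 0.015), lost their calls without tag control replicate 3. There they were at -1.09 (edgeR adjusted p = 0.0827) and -0.92 (0.145). The copies of mir-1829 share sequence and the table holds values that are multiples of 0.5, so how reads divide between the a, b and c rows is uncertain. The family's median was -1.87, and its direction turned under total count (TMM -0.15, DESeq2 size factors -0.081, total count 0.42). Under TMM, DESeq2 size factors and total count, mir-1829a_5p was above the control (0.35, 0.43 and 0.94), and called higher under the last (edgeR adjusted p = 8.2e-04). So placed, without a call, were mir-1829b_3p* (0.25, 0.32 and 0.82) and mir-1829c_3p* (0.31, 0.38 and 0.87). Under total count mir-1829a_3p* was at 0.030.

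Of the mir-35 family, miRNAs of oocytes and embryos, 11 of 16 rows fell, with a median of -2.0 (TMM -0.41, DESeq2 size factors -0.33, total count 0.17). Among them were mir-35_3p (-3.46 ± 0.46, edgeR adjusted p = 3.3e-06) and mir-41_3p (-3.71 ± 0.44, edgeR adjusted p = 8.1e-07). Of the mir-58 (bantam) family, 7 of 9 fell, with a median of -1.65 (TMM -0.020, DESeq2 size factors 0.057, total count 0.54). Its member mir-80_3p fell (-1.83 ± 0.36, edgeR adjusted p = 1.7e-04), with 0.45 under total count. In the let-7 family, 10 of 12 fell, with a median of -1.34 (TMM 0.38, DESeq2 size factors 0.46, total count 0.96). In the mir-51 family it was 6 of 12, with a median of -1.43 (TMM 0.17, DESeq2 size factors 0.25, total count 0.75). Its member mir-51_5p fell (-2.01 ± 0.31, edgeR adjusted p = 1.7e-05), with 0.26 under total count.

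Of miRNAs of muscle, neurons and other somatic tissues, 10 of 15 fell, with a median of -1.34 (TMM 0.31, DESeq2 size factors 0.38, total count 0.88). The muscle miRNA mir-1_3p was among them (-1.84 ± 0.38, edgeR adjusted p = 2.9e-04), with 0.45 under total count. The mirtron mir-62_3p, cut by splicing in place of the Microprocessor, fell (-1.82 ± 0.42, edgeR adjusted p = 7.9e-04), and also turned under total count (TMM -0.18, DESeq2 size factors -0.092, total count 0.43). Against the other miRNAs, no list stood apart by camera: for the mir-1829 and the mir-35 family, camera adjusted p = 0.543, or p = 0.894 with an estimated correlation. Camera placed the let-7, mir-51, bantam and somatic lists above the rest, although their medians were negative. The camera adjusted p of these 4 was 0.404, 0.505, 0.74 and 0.282, or 0.894 with an estimated correlation for each.

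In total 179 of 229 tested miRNAs were lower and 0 higher by edgeR (unadjusted p under 0.05: 180 and 0, DESeq2 180 and 0), with a median of -1.75. The other scalings, which set the average miRNA or the total to no change, moved the median to -0.067 (TMM, 47 lower and 28 higher), 0.010 (DESeq2 size factors, 44 and 35) and 0.53 (total count, 30 and 108).

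**Figure D1:**
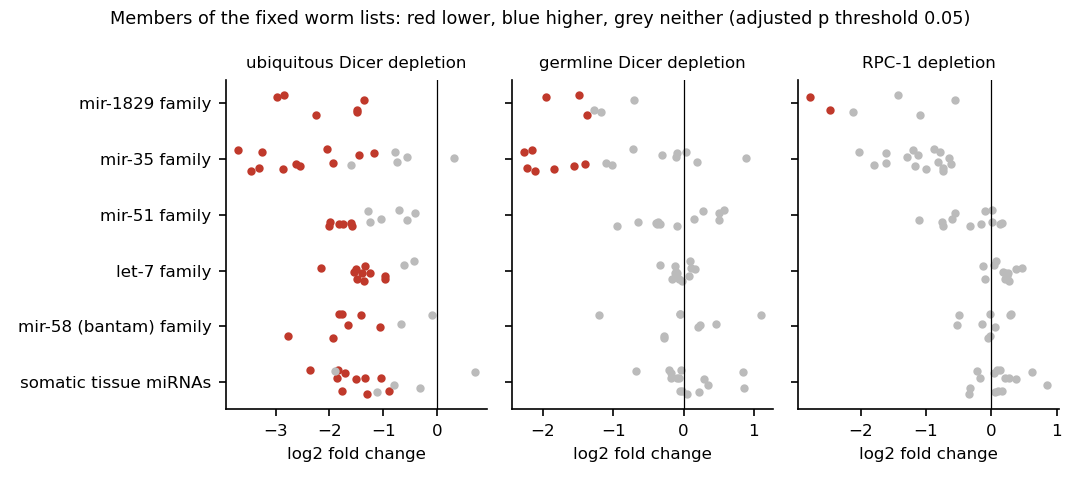
Log2 fold changes of the members of 6 fixed worm lists after ubiquitous Dicer, germline Dicer and RPC-1 depletion on the spike-in scale (red lower, blue higher, grey neither by edgeR). After ubiquitous Dicer depletion the medians of the let-7, mir-51 and somatic lists turn positive under TMM, that of the bantam list under DESeq2 size factors, and all 6 under total count, while after germline depletion those of the let-7, bantam and somatic lists, and after RPC-1 depletion that of the bantam list, turn positive under TMM, and that of the mir-51 list after germline depletion under total count.

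Germline Dicer depletion lowered part of the mir-35 and of the mir-1829 family. In the first, of oocytes and embryos, mir-40_3p fell from 58655 ± 5251 to 12159.8 ± 2091 (-2.27 ± 0.34, edgeR adjusted p = 1.6e-04) and mir-37_3p from 309271 ± 9284 to 65916 ± 12939 (-2.23 ± 0.38, edgeR adjusted p = 4.8e-04). Falls were also called for mir-35_3p (-2.1 ± 0.44, edgeR adjusted p = 0.00269) and mir-41_3p (-2.16 ± 0.41, edgeR adjusted p = 0.00126). Altogether 7 of 16 rows of this family fell and 0 rose by edgeR, 8 with the replicates paired. The median was -1.06 (TMM -0.95, DESeq2 size factors -0.85, total count -0.60), with camera adjusted p = 1.9e-05, or p = 0.47 with an estimated correlation.

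Of the mir-1829 family, 3 of 6 rows fell and 0 rose, with a median of -1.32 (TMM -1.17, DESeq2 size factors -1.07, total count -0.80). It was 5 when adjusted over the list alone, and 5 with the replicates paired. As a set the family had camera adjusted p = 9.5e-05, or p = 0.296 with an estimated correlation. The arm mir-1829b_5p fell from 55.3 ± 2.8 to 14.3 ± 1.88 (-1.95 ± 0.38, edgeR adjusted p = 0.00126). Falls were called for mir-1829a_3p* (-1.37 ± 0.37, edgeR adjusted p = 0.0233) and mir-1829c_5p (-1.49 ± 0.40, edgeR adjusted p = 0.024), but each call ended without any 1 of tag control replicates 1 and 2 and germline replicates 1, 2 and 3. The edgeR adjusted p was then 0.0835, 0.0956, 0.0619, 0.106 and 0.134 for mir-1829a_3p*, in that order, and 0.0792, 0.108, 0.0619, 0.106 and 0.15 for mir-1829c_5p. With the replicates paired both passed (edgeR adjusted p = 1.9e-04 and 3.6e-04). Paired, mir-1829c_3p* (-1.27 ± 0.52, edgeR adjusted p = 0.206) and mir-1829a_5p (-0.71 ± 0.41, edgeR adjusted p = 0.627) passed as well (edgeR adjusted p = 0.00861 and 0.00508). The remaining arm, mir-1829b_3p*, did not pass (-1.17 ± 0.53, edgeR adjusted p = 0.341).

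Further falls were called for mir-38_3p, also of the mir-35 family (-1.56 ± 0.44, edgeR adjusted p = 0.0286), mir-796_5p (-1.9 ± 0.45, edgeR adjusted p = 0.010) and mir-250_3p (-1.41 ± 0.43, edgeR adjusted p = 0.0485). The call of mir-796_5p ended without tag control replicate 2 or germline replicate 3 (edgeR adjusted p = 0.0778 and 0.0817). That of mir-38_3p ended without tag control 1 or 2 or germline 1, 2 or 3 (0.0792, 0.0956, 0.0811, 0.0864 and 0.162). That of mir-250_3p ended without any 1 of the 6 libraries (0.0792, 0.116, 0.139, 0.0919, 0.129 and 0.218 for tag control and then germline 1, 2 and 3). With the replicates paired all 3 passed (edgeR adjusted p = 4.0e-04, 0.0172 and 6.8e-04).

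The somatic miRNAs held 0 calls in either direction among 15 by edgeR, with a median of -0.033 and a mean of 0.073 (0.074, 0.18 and 0.46 on the other scales). The muscle miRNA mir-1_3p (-0.033 ± 0.37, edgeR adjusted p = 0.981) was at 0.10 without tag control replicate 1 and 0.073 without germline 3. Values near 0 were also those of let-7_5p (-0.087 ± 0.40, edgeR adjusted p = 0.981), mir-71_5p (-0.038 ± 0.37, edgeR adjusted p = 0.981) and mir-80_3p (-0.055 ± 0.35, edgeR adjusted p = 0.981). Without tag control 3 or germline 2, let-7_5p was at 0.022 and 9.7e-04, and mir-71_5p at 0.011 and 0.014. Without tag control 2 or germline 3, mir-80_3p was at 0.011 and 0.069. The let-7 family had 0 of 12 called and a median of -0.074 (0.056, 0.16 and 0.43 on the other scales). The bantam family had 0 of 9 called (1 lower and 1 higher with the replicates paired), with a median of -0.054 and a mean of 0.015 (0.055, 0.16 and 0.44 on the other scales). For the mirtron mir-62 the value was -0.018 (0.054, 0.15 and 0.44 on the other scales). The mir-51 family had 0 of 12 called (median -0.21, 0.26 under total count), but 3 lower with the replicates paired, among them mir-51_5p (-0.95 ± 0.30, edgeR adjusted p = 0.0632) at a paired edgeR adjusted p of 3.6e-04. Camera placed the somatic, let-7, bantam and mir-51 lists above the other miRNAs (camera adjusted p = 0.146, 0.334, 0.334 and 0.713). With an estimated correlation the adjusted p was 0.859, 0.859, 0.859 and 0.897.

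In all, 16 miRNAs were lower and 0 higher by edgeR (unadjusted 25 and 2, DESeq2 18 and 2), and 44 and 1 with the replicates paired. The number lower was 9 without tag control replicate 1, 9 without tag control 2, 10 without germline 1, 9 without germline 2 and 9 without germline 3. The number higher was 2 under TMM, 4 under DESeq2 size factors, 22 under total count and 1 without germline 3. All 16 miRNAs called lower were also lower after ubiquitous depletion, against 12.5 for independent calls. The tag control is shared, so part of the excess may come from it. Simulations with no effect in either comparison (50) gave at most 0, a value that leaves out the effects.

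Set directly against germline depletion, ubiquitous Dicer depletion left 172 miRNAs lower and 0 higher (edgeR, unadjusted 176 and 0, DESeq2 178 and 0). Large differences were seen in mir-235_3p (-4.68 ± 0.32, edgeR adjusted p = 5.6e-10) and mir-71_5p (-4.4 ± 0.42, edgeR adjusted p = 5.7e-08). The muscle miRNA mir-1_3p was lower (-1.81 ± 0.38, edgeR adjusted p = 6.3e-04), as was mir-62_3p (-1.8 ± 0.42, edgeR adjusted p = 0.0013). The timing miRNA let-7_5p was lower too (-1.31 ± 0.41, edgeR adjusted p = 0.00826), and turned (0.29, 0.26 and 0.50 on the other scales). By list, 10 of 15 somatic miRNAs were lower, with a median of -1.34 (0.14, 0.10 and 0.34 on the other scales). It was 9 of 12 for the let-7 family, with a median of -1.26 (0.33, 0.30 and 0.54 on the other scales). For the mir-51 family it was 8 of 12, with a median of -1.25 (0.24, 0.22 and 0.45 on the other scales), and for the bantam family 7 of 9, with -1.66 (-0.072, -0.10 and 0.14 on the other scales). Camera placed the somatic, let-7 and mir-51 lists above the other miRNAs (camera adjusted p = 0.408, or p = 0.829 with an estimated correlation, for each). Under TMM the totals were 29 lower and 23 higher, under DESeq2 size factors 27 and 21, and under total count 19 and 45.

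In the mir-35 family 9 of 16 rows were lower, with a median of -1.01 (0.49, 0.46 and 0.70 on the other scales). Its member mir-35_3p was lower (-1.35 ± 0.43, edgeR adjusted p = 0.00845), and turned (0.11, 0.092 and 0.32 on the other scales). In the mir-1829 family it was 3 of 6, with a median of -0.76 (0.82, 0.79 and 1.03 on the other scales). Camera placed both families above the other miRNAs although their medians were negative (camera adjusted p = 0.0911, or p = 0.829 with an estimated correlation, for each). Lower were mir-1829c_5p (-1.36 ± 0.40, edgeR adjusted p = 0.00654), mir-1829b_5p (-1.02 ± 0.38, edgeR adjusted p = 0.0198) and mir-1829a_3p* (-0.88 ± 0.36, edgeR adjusted p = 0.0334). Not called were mir-1829a_5p (-0.65 ± 0.41, edgeR adjusted p = 0.158), mir-1829b_3p* (-0.31 ± 0.53, edgeR adjusted p = 0.586) and mir-1829c_3p* (-0.22 ± 0.51, edgeR adjusted p = 0.697), the last at 0.21 without germline replicate 3. On the other scales all 6 rows were positive, with 2, 2 and 5 called higher, mir-1829a_3p* on each. The call of mir-1829b_5p ended without ubiquitous replicate 1 or germline 1 (edgeR adjusted p = 0.0559 and 0.0658). That of mir-1829a_3p* ended without ubiquitous 2 or 3 or germline 1 or 2 (0.0718, 0.107, 0.108 and 0.0694).

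RPC-1 depletion lowered 2 of 6 rows of the mir-1829 family, 5 under TMM, DESeq2 size factors and total count and 4 under DESeq2 size factors on the spike-ins. The arm mir-1829b_5p fell from 56 ± 18.3 in the TIR1-only control to 8.1 ± 0.691 (-2.78 ± 0.39, edgeR adjusted p = 1.2e-04), and mir-1829c_3p* from 27.2 ± 17.6 to 4.83 ± 1.33 (-2.48 ± 0.55, edgeR adjusted p = 0.024). The second call rests on few counts and ended without TIR1-only replicate 2 or 3 or RPC-1 replicate 1 or 2 (edgeR adjusted p = 0.0704, 0.314, 0.186 and 0.23). Over all miRNAs the other 4 rows did not pass. These were mir-1829b_3p* (-2.11 ± 0.56, edgeR adjusted p = 0.062), mir-1829c_5p (-1.43 ± 0.40, edgeR adjusted p = 0.087), mir-1829a_3p* (-1.1 ± 0.36, edgeR adjusted p = 0.172) and mir-1829a_5p (-0.56 ± 0.41, edgeR adjusted p = 0.918). Without TIR1-only replicate 1, mir-1829b_3p* and mir-1829c_5p passed (edgeR adjusted p = 0.00989 and 0.0361). Without RPC-1 replicate 3, these and mir-1829a_3p* passed (0.0223, 0.0153 and 0.0288). Adjusted over the list alone, 5 of 6 rows were lower. The family's median was -1.77 (TMM -1.62, DESeq2 size factors -1.67, total count -1.68), with camera adjusted p = 9.7e-13, or p = 0.0138 with an estimated correlation.

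The mir-35 family, of oocytes and embryos, had 0 of 16 rows called over all miRNAs and 6 lower when adjusted over the list alone. Its median was -1.06 (TMM -0.88, DESeq2 size factors -0.91, total count -0.92), with camera adjusted p = 8.4e-11, or p = 0.149 with an estimated correlation. Under TMM 6 of its rows were lower, and under DESeq2 size factors 8. Its members mir-36_3p (-0.99 ± 0.34, edgeR adjusted p = 0.185) and mir-35_3p (-0.73 ± 0.42, edgeR adjusted p = 0.761) did not pass. The somatic miRNAs let-7_5p (0.26 ± 0.40, edgeR adjusted p = 0.984), mir-1_3p (0.094 ± 0.37, edgeR adjusted p = 0.984) and mir-71_5p (0.035 ± 0.37, edgeR adjusted p = 0.987) did not pass either. Without RPC-1 replicate 3 these 3 turned negative (-0.50, -0.35 and -0.41). The last 2 did so without TIR1-only replicate 1 (-0.12 and -0.19) or 2 (-0.11 and -0.17). By edgeR the let-7, somatic, mir-51 and bantam lists and the mirtron held 0 calls. Their medians were 0.21 (camera adjusted p = 0.031, or p = 0.631 with an estimated correlation), 0.11 (camera adjusted p = 0.0553, or p = 0.631 with an estimated correlation), -0.24, -0.020 (0.17, 0.12 and 0.11 on the other scales) and -0.56. Camera placed the bantam list above the other miRNAs (camera adjusted p = 0.491, or p = 0.809 with an estimated correlation).

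After RPC-1 depletion 2 miRNAs were lower and 0 higher (edgeR, unadjusted 20 and 0, DESeq2 7 and 0, replicate block 20 and 4). The number lower was 9 without TIR1-only replicate 1 and 13 without RPC-1 replicate 3, whose genotype as given lacks the degron allele. It was 1 without TIR1-only 2 or 3 or RPC-1 1 or 2. Under TMM 13 were lower and 2 higher, under DESeq2 size factors 17 and 2, and under total count 17 and 4. DESeq2 size factors on the spike-ins gave 5 and 0, with mir-71_5p at -9.2e-04. Both miRNAs called, mir-1829b_5p and mir-1829c_3p*, were also lower after ubiquitous Dicer depletion. This overlap of 2 compares with 1.56 for independent calls, and the 2 comparisons share no library. It was 5 without ubiquitous Dicer 3, 8 without TIR1-only 1, 10 without RPC-1 replicate 3 and 20 with the block. Without tag control 3, TIR1-only 2 or 3 or RPC-1 1 or 2 it was 1.

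**Figure D2:**
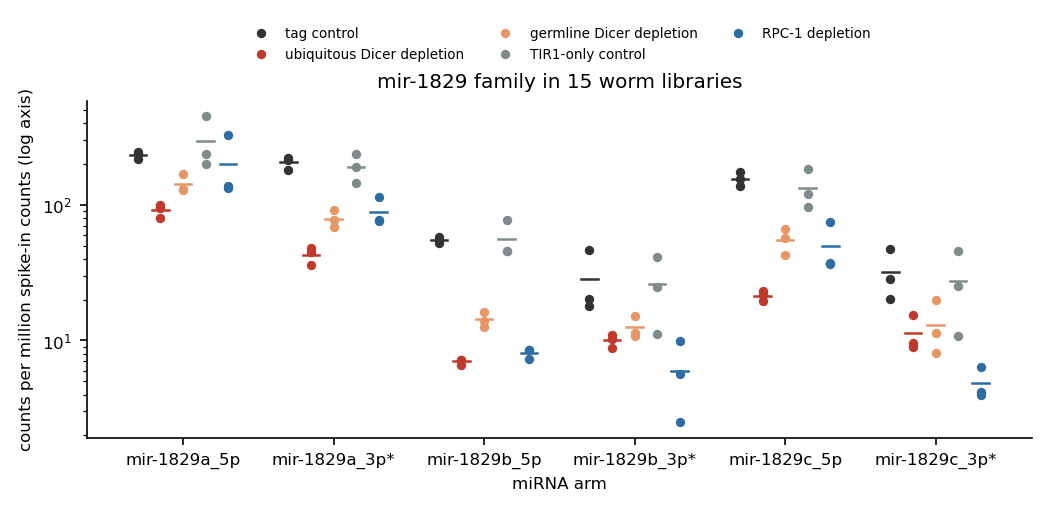
Levels of the 6 mir-1829 rows in each worm library, in counts per 1000000 spike-in counts, with group means. Under TMM, DESeq2 size factors and total count the family's median is higher after ubiquitous than after germline Dicer depletion, and under total count it is also higher than in the tag control.

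Between the 2 worm control strains, TIR1-only and tag, no mir-1829 row passed. The 5p arms were mir-1829a_5p (0.34 ± 0.41, edgeR adjusted p = 0.661), mir-1829b_5p (0.013 ± 0.36, edgeR adjusted p = 0.997) and mir-1829c_5p (-0.22 ± 0.39, edgeR adjusted p = 0.786). The 3p arms were mir-1829a_3p* (-0.10 ± 0.36, edgeR adjusted p = 0.882), mir-1829b_3p* (-0.14 ± 0.52, edgeR adjusted p = 0.886) and mir-1829c_3p* (-0.24 ± 0.51, edgeR adjusted p = 0.792). Their signs moved with single libraries. Without TIR1-only replicate 3, mir-1829a_5p was at -0.10 and mir-1829b_5p at -0.28, and mir-1829b_5p was at -0.023 without tag control 2. Without TIR1-only 1, mir-1829a_3p*, mir-1829b_3p* and mir-1829c_3p* were at 0.060, 0.23 and 0.15, and without tag control 3 the last 2 were at 0.42 and 0.15. The family's median was -0.12 (TMM 0.014, DESeq2 size factors 0.040, total count -0.049), while camera placed it above the other miRNAs (camera adjusted p = 0.585, or p = 0.865 with an estimated correlation). The let-7 list had a median of 0.45 (TMM 0.59, DESeq2 size factors 0.62, total count 0.51), with camera adjusted p = 5.5e-05, or p = 0.865 with an estimated correlation. The mir-35 list had a median of -0.54, with camera adjusted p = 0.0275, or p = 0.865 with an estimated correlation. Medians of the mir-51, bantam, somatic and mirtron lists were -0.57, -0.14 (0.078, 0.11 and 0.020 on the other scales), -0.63 and -0.83. Camera placed the bantam list above the other miRNAs (camera adjusted p = 0.67, or p = 0.865 with an estimated correlation). Over all miRNAs edgeR called 0 lower and 0 higher (unadjusted 14 and 5, DESeq2 0 and 0). The other scalings gave 0 and 15 (TMM), 1 and 16 (DESeq2 size factors) and 6 and 13 (total count).

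In RKO cells transduced with guide RNAs, Cas9 was induced against Dicer or DGCR8, the RNA-binding partner of Drosha in the Microprocessor complex. The wild type label names no guide, so against wild type, transduction and cutting are not separated from loss of either protein. Other cells were treated with a Pol III inhibitor. Deposited values summed to 15665624 ± 5947959 in wild type, 8704010 ± 2536176 in the Dicer knockout and 5345623 ± 3056322 in the DGCR8 knockout (mean ± SD, n = 4 each). Against wild type the exact permutation p was 0.0857 for Dicer and 0.0571 for DGCR8, and between the knockouts 0.171. Sums were 8593448 ± 3579832 with DMSO and 7236592 ± 1099842 with the inhibitor (exact permutation p = 0.80, n = 3 each). What the deposited size factors rest on is not stated. RKO results are therefore given relative to the other miRNAs, by limma on TMM-scaled reads, and most then on the deposited scale ("deposited"). Levels are TMM-scaled reads, and the log2 fold changes, taken after adding 5, understate those of miRNAs with few reads. Adjusted p-values of RKO miRNAs are from limma unless another tool is named.

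Relative to the other miRNAs, the Dicer knockout lowered miR-3929, several arms of mirtrons and the arms of miR-301 named here. The miRNA miR-3929 fell from 146 ± 20.7 in wild type to 27.9 ± 8.3 (-2.22 ± 0.24, adjusted p = 1.5e-06, deposited -3.11), and miR-301b-5p from 93.3 ± 15.5 to 17.9 ± 4.54 (-2.11 ± 0.21, adjusted p = 9.4e-07, deposited -2.98). Both arms of the mirtron miR-1228 fell, 5p (-1.87 ± 0.25, adjusted p = 2.0e-05, deposited -2.76) and 3p (-1.8 ± 0.42, adjusted p = 0.00568, deposited -2.6). The mirtron miR-1226-3p fell as well (-1.75 ± 0.18, adjusted p = 1.2e-06, deposited -2.65). Of the miR-130 family, miR-301a-3p (-0.95 ± 0.13, adjusted p = 2.3e-05, deposited -1.87) and miR-301b-3p (-1.02 ± 0.12, adjusted p = 8.0e-06, deposited -1.94) fell, near copies for which the division of reads is uncertain. The falls of miR-6844 (-1.07 ± 0.26, adjusted p = 0.0058, deposited -1.96) and miR-1277-5p (-0.77 ± 0.16, adjusted p = 0.00196, deposited -1.68) were smaller. These were lower on the deposited scale too.

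A large rise relative to the other miRNAs was that of miR-642a-3p, from 23.2 ± 4.9 to 121 ± 23.4 (2.16 ± 0.28, adjusted p = 1.3e-05, deposited 1.36). Of the 53 miRNAs called higher, 1 was called higher on the deposited scale. Some lay below wild type there, as did miR-361-3p (0.80 ± 0.16, adjusted p = 0.00132, deposited -0.12). The same held for the cell-cycle miRNA miR-16-5p (0.45 ± 0.12, adjusted p = 0.0114, deposited -0.48). The call of miR-16-5p ended without Dicer replicate 4 (limma adjusted p = 0.0612). Neither the abundant miR-21-5p (-0.053 ± 0.14, adjusted p = 0.831, deposited -0.98) nor miR-484 (-0.056 ± 0.13, adjusted p = 0.794, deposited -0.98) passed relative to the others, but miR-484 was lower by the deposited values (limma adjusted p = 0.0252). Without Dicer replicate 1 miR-21-5p was at 0.090, and without Dicer replicate 2 miR-484 was at 0.0011.

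Of the mirtrons, 5 of 10 were lower and 0 higher (median -0.85), and 8 and 0 on the deposited scale (median -1.53). Their camera test gave camera adjusted p = 0.00143, or p = 0.133 with an estimated correlation. Of the let-7 family, 4 of 19 were lower and 0 higher (median -0.30), and 15 and 0 on the deposited scale (median -1.1). Among these was let-7i-5p (-0.63 ± 0.15, adjusted p = 0.00641, deposited -1.56), and the list had camera adjusted p = 0.0342, or p = 0.193 with an estimated correlation. Of the miR-15/16 family, 0 of 9 were lower and 4 higher (median 0.38), and 1 and 0 on the deposited scale (median -0.54). Its test gave camera adjusted p = 0.0121, or p = 0.198 with an estimated correlation. Of the miR-200 family, of epithelial cells, 1 of 6 were lower and 1 higher (median 0.11), and 2 and 0 on the deposited scale (median -0.80). The member miR-429 was lower (-0.51 ± 0.12, adjusted p = 0.00587, deposited -1.44). Of the miR-17-92 and paralogous clusters, 0 of 21 were lower and 3 higher (median 0.13), and 5 and 0 on the deposited scale (median -0.77). Of hairpins made from capped transcripts without the Microprocessor, 0 of 3 were lower and 0 higher (median 0.28), and 1 and 0 on the deposited scale (median -0.52). Of snoRNA-derived miRNAs, 0 of 5 were lower and 2 higher (median 0.67), and 0 and 0 on the deposited scale (median -0.25). The snoRNA-derived miR-664a-3p was higher (0.67 ± 0.12, adjusted p = 5.0e-04, deposited -0.25), and the list had camera adjusted p = 0.0342, or p = 0.193 with an estimated correlation. Of miRNAs from tRNA and other Pol III RNAs, 0 of 3 were lower and 1 higher (median 0.64), and 0 and 0 on the deposited scale (median -0.26). Among these miR-4454 (0.64 ± 0.18, adjusted p = 0.0197, deposited -0.26) lost its call without wild type replicate 3 or Dicer replicate 4 (limma adjusted p = 0.0719 and 0.061). Of the chromosome 19 cluster, 0 of 5 were lower and 0 higher (median 0.10), and 2 and 0 on the deposited scale (median -0.79), with -0.0063 under total count. Of miRNAs of other tissues, 0 of 3 were lower and 0 higher (median 0.032), and 0 and 0 on the deposited scale (median -0.71), with -0.010 under DESeq2 size factors and -0.067 under total count. The mean of this list was -0.044. The Dicer-independent miRNA did not pass (limma, -0.60, deposited -1.18).

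The limma test called 72 miRNAs lower and 53 higher of 639 (median -0.013), and 246 lower and 1 higher on the deposited scale (median -0.80). The number higher was 33 without wild type replicate 2, 32 without wild type 3, 32 without Dicer replicate 3 and 25 without Dicer 4. It was 30 under total count, 14 with no filter and 34 without the 4 libraries in which 1 read is worth most.

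**Figure D3:**
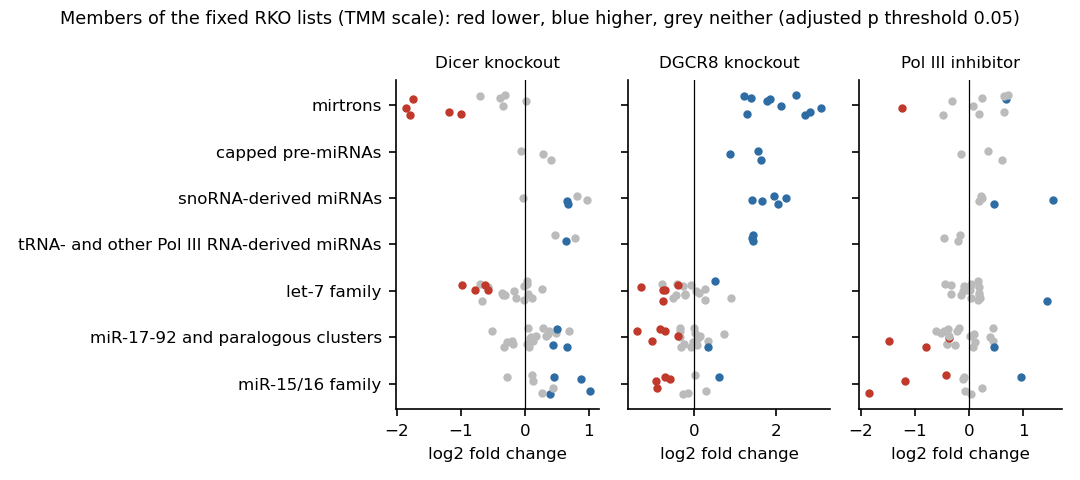
Log2 fold changes of the members of fixed human lists relative to the other miRNAs. On the deposited scale the medians of the capped and tRNA-derived lists in the DGCR8 knockout, and of the snoRNA-derived, tRNA-derived, capped, miR-15/16 and miR-17-92 lists in the Dicer knockout and of the let-7 list with the inhibitor, turn negative, and under DESeq2 size factors that of the miR-17-92 list in the DGCR8 knockout turns positive.

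In the DGCR8 knockout, miRNAs whose hairpins bypass the Microprocessor rose relative to the rest. The mirtron miR-1228-5p went from 107 ± 11.4 in wild type to 995 ± 338 (3.09 ± 0.25, adjusted p = 2.4e-08, deposited 1.51). Other mirtrons higher on both scales were miR-1228-3p (2.7 ± 0.42, adjusted p = 4.7e-05, deposited 1.21), miR-1229-3p (2.8 ± 0.28, adjusted p = 1.9e-07, deposited 1.41) and miR-877-5p (2.47 ± 0.29, adjusted p = 1.7e-06, deposited 0.89). Of the mirtrons 10 of 10 rose (median 1.98), and 6 on the deposited scale (median 0.97). The list had camera adjusted p = 9.6e-06, or p = 0.0265 with an estimated correlation. Of the snoRNA-derived miRNAs 5 of 5 rose (median 1.95), and 0 on the deposited scale (median 0.43). The list had camera adjusted p = 0.00174, or p = 0.0459 with an estimated correlation. These include miR-664a-3p (2.03 ± 0.12, adjusted p = 2.9e-10, deposited 0.43) and miR-664b-3p (1.64 ± 0.22, adjusted p = 7.7e-06, deposited 0.071). Of the capped hairpins 3 of 3 rose (median 1.55), and 0 on the deposited scale (median -0.049). The list had camera adjusted p = 0.0263, or p = 0.149 with an estimated correlation. These include miR-484 (1.55 ± 0.13, adjusted p = 2.4e-08, deposited -0.056) and miR-320a-3p (1.61 ± 0.21, adjusted p = 6.5e-06, deposited 0.0061).

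Of miRNAs from tRNA and other Pol III RNAs 3 of 3 rose (median 1.42), and 0 on the deposited scale (median -0.074). The list had camera adjusted p = 0.0307, or p = 0.224 with an estimated correlation. They are miR-4454 (1.42 ± 0.18, adjusted p = 4.1e-06, deposited -0.14), miR-1260a (1.42 ± 0.31, adjusted p = 9.0e-04, deposited 0.011) and miR-1260b (1.42 ± 0.23, adjusted p = 5.9e-05, deposited -0.074), the last 2 near copies. Large rises relative to the others were also those of miR-3615 (2.04 ± 0.17, adjusted p = 2.4e-08, deposited 0.45) and miR-6516-5p (2.4 ± 0.23, adjusted p = 1.6e-07, deposited 0.86). Of these, miR-6516-5p passed on the deposited scale (limma adjusted p = 0.0346) and miR-3615 did not (0.31).

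Large falls, seen on both scales, were those of miR-589-3p (-1.81 ± 0.18, adjusted p = 1.9e-07, deposited -3.26) and miR-671-5p (-1.78 ± 0.34, adjusted p = 5.5e-04, deposited -3.39). Of the let-7 family, 5 of 19 were lower and 1 higher (median -0.28), and 18 and 0 on the deposited scale (median -1.84). Of the miR-17-92 and paralogous clusters, 5 of 21 were lower and 1 higher (median -0.079), and 19 and 0 on the deposited scale (median -1.68), with 0.0027 under DESeq2 size factors. Of the miR-15/16 family, 4 of 9 were lower and 1 higher (median -0.28), and 9 and 0 on the deposited scale (median -1.89). Of the miR-200 family, 0 of 6 were lower and 1 higher (median 0.021), and 6 and 0 on the deposited scale (median -1.59). Relative to the others let-7a-5p (0.52 ± 0.12, adjusted p = 0.00116, deposited -1.09) and miR-16-5p (0.60 ± 0.12, adjusted p = 3.4e-04, deposited -1.01) were higher. By the deposited values they were lower (limma adjusted p = 0.0184 and 0.0265). Not called relative to the others were miR-21-5p (-0.14 ± 0.14, adjusted p = 0.431, deposited -1.75), miR-1277-5p (-0.11 ± 0.16, adjusted p = 0.584, deposited -1.69), miR-301a-3p (0.10 ± 0.13, adjusted p = 0.514, deposited -1.5) and miR-301b-3p (0.0052 ± 0.12, adjusted p = 0.975, deposited -1.59). By the deposited values all 4 were lower (limma adjusted p = 4.4e-04, 8.1e-05, 3.9e-04 and 2.1e-04). Relative to the others miR-301b-3p was negative without wild type replicate 2 (-0.056), 3 (-0.069) or 4 (-0.030) or DGCR8 replicate 2 (-0.076). Of the chromosome 19 cluster, 0 of 5 were lower and 1 higher (median 0.54), and 4 and 0 on the deposited scale (median -0.89). Of miRNAs of other tissues, 0 of 3 were lower and 0 higher (median -0.43), and 2 and 0 on the deposited scale (median -1.61). The Dicer-independent miRNA did not pass (limma, -0.61, deposited -1.62).

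In total 162 were lower and 177 higher by limma (median -0.15), and 422 and 19 on the deposited scale (median -1.53). Opposite directions were called for 21 miRNAs. With a mean deposited value of at least 50 the numbers were 100 and 62, and with no filter 282 were lower. In both knockouts 29 miRNAs were lower, against 18.3 for independent calls (177 against 162 on the deposited scale). In 50 simulations, which leave out all effects, it was at most 0. With the 4 wild type libraries divided between the knockouts, the overlap was 15 to 17 over 6 divisions (mean 16, with 8.94 expected).

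Set against the Dicer knockout, the DGCR8 knockout held more of each tested mirtron. The mirtron miR-1228-5p was 995 ± 338 with DGCR8 removed and 26.2 ± 6.45 with Dicer removed (4.95 ± 0.25, adjusted p = 1.0e-11, deposited 4.27). A difference was also called for miR-1226-3p (3.59 ± 0.18, adjusted p = 1.0e-11, deposited 2.91). Of the mirtrons, 0 of 10 were lower and 10 higher (median 2.62), and 0 and 10 on the deposited scale (median 2.02). Their test gave camera adjusted p = 1.5e-06, or p = 0.0158 with an estimated correlation. Higher on both scales were miR-3929 (3.65 ± 0.24, adjusted p = 4.9e-10, deposited 2.96) and miR-6844 (3.18 ± 0.26, adjusted p = 4.7e-09, deposited 2.5). Of the snoRNA-derived miRNAs, 0 of 5 were lower and 4 higher (median 1.14), and 0 and 1 on the deposited scale (median 0.50). This list had camera adjusted p = 0.042, or p = 0.266 with an estimated correlation. Of the capped hairpins, 0 of 3 were lower and 2 higher (median 1.21), and 0 and 1 on the deposited scale (median 0.52). The capped miR-484 was higher on both scales (1.61 ± 0.13, adjusted p = 4.5e-09, deposited 0.93). Of miRNAs from tRNA and other Pol III RNAs, 0 of 3 were lower and 2 higher (median 0.79), and 0 and 0 on the deposited scale (median 0.12). Their member miR-4454 was higher (0.79 ± 0.18, adjusted p = 0.00115, deposited 0.12).

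Higher relative to the other miRNAs in the DGCR8 than in the Dicer knockout were also miR-301a-3p (1.05 ± 0.13, adjusted p = 1.3e-06, deposited 0.38), miR-301b-3p (1.02 ± 0.12, adjusted p = 1.1e-06, deposited 0.35), miR-1277-5p (0.66 ± 0.16, adjusted p = 0.00165, deposited -0.0094) and miR-429 (0.43 ± 0.12, adjusted p = 0.00588, deposited -0.25). By the deposited values they were not called (limma adjusted p = 0.377, 0.413, 0.982 and 0.585). Lower were miR-642a-3p (-2.62 ± 0.28, adjusted p = 1.9e-07, deposited -3.01) and miR-153-5p (-2.01 ± 0.15, adjusted p = 1.2e-09, deposited -2.67). Of the miR-17-92 and paralogous clusters, 10 of 21 were lower and 0 higher (median -0.31), and 11 and 0 on the deposited scale (median -1.0). Of the miR-15/16 family, 6 of 9 were lower and 0 higher (median -0.66), and 7 and 0 on the deposited scale (median -1.35). This family had camera adjusted p = 0.0351, or p = 0.287 with an estimated correlation, and miR-16-5p did not pass (0.15 ± 0.12, adjusted p = 0.293, deposited -0.53). Of the let-7 family, 1 of 19 were lower and 3 higher (median -0.012), and 6 and 0 on the deposited scale (median -0.61), with 0.12 under DESeq2 size factors and 0.10 under total count. The mean of this list was 0.052. Camera placed it above the other miRNAs (camera adjusted p = 0.819, or p = 0.876 with an estimated correlation). Of the miR-200 family, 1 of 6 were lower and 2 higher (median 0.093), and 2 and 0 on the deposited scale (median -0.58). The mean of this list was -0.11. Camera placed it below the other miRNAs (camera adjusted p = 0.819, or p = 0.876 with an estimated correlation). Of the chromosome 19 cluster, 0 of 5 were lower and 2 higher (median 0.45), and 0 and 0 on the deposited scale (median -0.17). Of miRNAs of other tissues, 0 of 3 were lower and 0 higher (median -0.44), and 2 and 0 on the deposited scale (median -0.91). The Dicer-independent miRNA did not pass (limma, -0.014, deposited -0.44, 0.011 under DESeq2 size factors and 0.026 under total count).

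Between the knockouts limma called 183 lower and 177 higher, and 249 and 101 on the deposited scale. With a mean deposited value of at least 50 the numbers were 111 and 87. Of the 72 miRNAs lower in the Dicer knockout, 43 were higher in the DGCR8 than in the Dicer knockout, against 19.9 for independent calls (63 against 38.9 on the deposited scale). Simulations that leave out all effects (50) gave at most 0. With the Dicer libraries divided between the comparisons, there were 24 to 32 (mean 27.2, with 12.2 expected). Of the 43, 39 were not lower in the DGCR8 knockout than in wild type, 26 of them by the deposited values too.

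The Pol III inhibitor lowered miR-4521 and raised miR-3929 on both scales. The first fell from 17709.6 ± 4605 with DMSO to 5269 ± 1505 (-1.76 ± 0.35, adjusted p = 0.00461, deposited -1.9 at adjusted p = 0.0172). The second rose (1.73 ± 0.28, adjusted p = 3.3e-04, deposited 1.63 at 0.0353). Its levels were low (DMSO 7.91 to 20.8, inhibitor 47.7 to 81, wild type 125 to 166). Both arms of miR-1277 fell, 3p (-1.88 ± 0.29, adjusted p = 3.3e-04, deposited -2.01) and 5p (-1.52 ± 0.18, adjusted p = 2.8e-05, deposited -1.66). The passenger arm miR-16-1-3p fell on both scales (-1.85 ± 0.20, adjusted p = 9.3e-06, deposited -1.99). Relative to the other miRNAs, miR-153-3p (-1.35 ± 0.17, adjusted p = 3.4e-05, deposited -1.49) and miR-190a-5p (-1.38 ± 0.20, adjusted p = 1.8e-04, deposited -1.52) fell. On the deposited scale these were not called (limma adjusted p = 0.0606 and 0.0763). Higher relative to the others was let-7d-3p (1.44 ± 0.28, adjusted p = 0.00226, deposited 1.29), not called on the deposited scale (0.0606).

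Of miRNAs from tRNA and other Pol III RNAs, 0 of 3 were lower and 0 higher (median -0.20), and 0 and 0 on the deposited scale (median -0.34). They are miR-4454 (-0.20 ± 0.21, adjusted p = 0.639, deposited -0.34), miR-1260a (-0.46 ± 0.36, adjusted p = 0.488, deposited -0.60) and miR-1260b (-0.16 ± 0.27, adjusted p = 0.802, deposited -0.29), the last at 0.042 without inhibitor replicate 2. Of the miR-17-92 and paralogous clusters, 3 of 21 were lower and 1 higher (median -0.25), and 1 and 0 on the deposited scale (median -0.39). Their member miR-19a-3p was lower (-0.79 ± 0.16, adjusted p = 0.00284, deposited -0.93). Of the miR-15/16 family, 3 of 9 were lower and 1 higher (median -0.092), and 1 and 0 on the deposited scale (median -0.24). Of the miR-200 family, 1 of 6 were lower and 1 higher (median -0.017), and 0 and 0 on the deposited scale (median -0.16), with 0.013 under total count. Its member miR-141-3p was lower (-1.17 ± 0.19, adjusted p = 3.5e-04, deposited -1.31). Of the let-7 family, 0 of 19 were lower and 1 higher (median 0.033), and 0 and 0 on the deposited scale (median -0.11), with -0.070 under DESeq2 size factors. Camera placed it below the other miRNAs (camera adjusted p = 0.978, or p = 0.982 with an estimated correlation). Of the mirtrons, 1 of 10 were lower and 1 higher (median 0.21), and 0 and 0 on the deposited scale (median 0.10). Of the snoRNA-derived miRNAs, 0 of 5 were lower and 2 higher (median 0.24), and 0 and 0 on the deposited scale (median 0.13). Among these the call of miR-664a-3p ended without any 1 of the 6 libraries (limma adjusted p = 0.0786, 0.16, 0.151, 0.10, 0.26 and 0.0525 for DMSO and then inhibitor 1, 2 and 3). Of the capped hairpins, 0 of 3 were lower and 0 higher (median 0.35), and 0 and 0 on the deposited scale (median 0.21). The capped miR-484 did not pass (0.35 ± 0.15, adjusted p = 0.14, deposited 0.21). Of the chromosome 19 cluster, 1 of 5 were lower and 0 higher (median -0.24), and 0 and 0 on the deposited scale (median -0.34). This call, of miR-521, ended without DMSO replicate 2 or inhibitor replicate 1, 2 or 3 (limma adjusted p = 0.161, 0.0719, 0.0711 and 0.0553). Of miRNAs of other tissues, 0 of 3 were lower and 0 higher (median -0.17), and 0 and 0 on the deposited scale (median -0.28). Their mean was 0.26, and the Dicer-independent miRNA among them did not pass (limma, 1.52, deposited 1.45). By camera no list passed, the lowest camera adjusted p being 0.0772 for the miR-17-92 clusters (0.478 with an estimated correlation). The abundant miR-21-5p (-0.50 ± 0.17, adjusted p = 0.057, deposited -0.64) passed without inhibitor replicate 3 (limma adjusted p = 0.046).

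In all, 36 miRNAs were lower and 39 higher by limma, and 9 and 2 on the deposited scale. Single libraries moved these numbers. The number higher was 14, 5 and 20 without DMSO replicate 1, 2 and 3, and 22, 9 and 15 without inhibitor replicate 1, 2 and 3. The number lower was 23 without DMSO replicate 1. Under DESeq2 size factors 22 were higher, with no filter 7, and in a fit of the 6 libraries alone 4. It was 15 among miRNAs with a mean deposited value of at least 10. Without the 4 libraries in which 1 read is worth most it was 9.

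Lower in the Dicer knockout, lower with the inhibitor and higher in the DGCR8 than in the Dicer knockout were 5 miRNAs. They are miR-1228-5p, miR-1277-5p, miR-301a-3p, miR-301b-3p and miR-6844. The Dicer and inhibitor comparisons share no library, and 6 miRNAs were lower in both, against 4.06 for independent calls (4 against 3.46 on the deposited scale). With the inhibitor miR-1228-5p (-1.24 ± 0.29, adjusted p = 0.0089, deposited -1.36), miR-301a-3p (-0.99 ± 0.15, adjusted p = 1.8e-04, deposited -1.14), miR-301b-3p (-0.81 ± 0.14, adjusted p = 9.5e-04, deposited -0.95) and miR-6844 (-1.07 ± 0.30, adjusted p = 0.0258, deposited -1.2) fell less than miR-1277-5p. The inhibitor call of miR-6844 ended without DMSO replicate 1 or 2 or inhibitor replicate 2 (limma adjusted p = 0.0921, 0.0692 and 0.113). On the deposited scale 0 miRNAs met all 3 calls by limma. On the TMM scale edgeR on the recovered reads gave 5 and DESeq2 5, which does not bear on the choice of scale. By the GENCODE annotation, MIR1228 lies in an intron of LRP1, MIR1277 of WDR44, MIR301A of SKA2 and MIR301B of AP000553.1, and MIR6844 in an exon of TATDN1, each on the strand of its host.

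The loci of miR-4521 and miR-3929 lie in no annotated host gene (GRCh38, MIR4521 at chromosome 17, 8186945 to 8187004, plus strand, and MIR3929 at chromosome 18, 35934088 to 35934142, minus strand). Values of miR-4521 outside the inhibitor comparison, and of miR-3929 in the inhibitor and DGCR8 comparisons with their own controls, were chosen after the values of these miRNAs were seen. In the Dicer knockout miR-4521 did not pass (0.73 ± 0.30, adjusted p = 0.106, deposited -0.20), but did without Dicer replicate 2 (limma adjusted p = 0.0311). In the DGCR8 knockout it was higher relative to the others (1.59 ± 0.30, adjusted p = 4.5e-04, deposited -0.015), as it was against the Dicer knockout (0.87 ± 0.30, adjusted p = 0.0222, deposited 0.19). The last call ended without Dicer replicate 1 or 2 or DGCR8 replicate 3 or 4 (limma adjusted p = 0.075, 0.0893, 0.0509 and 0.0684). In the DGCR8 knockout miR-3929 was higher relative to the others (1.42 ± 0.24, adjusted p = 6.9e-05, deposited -0.15), and not called on the deposited scale (limma adjusted p = 0.752).

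**Figure D4:**
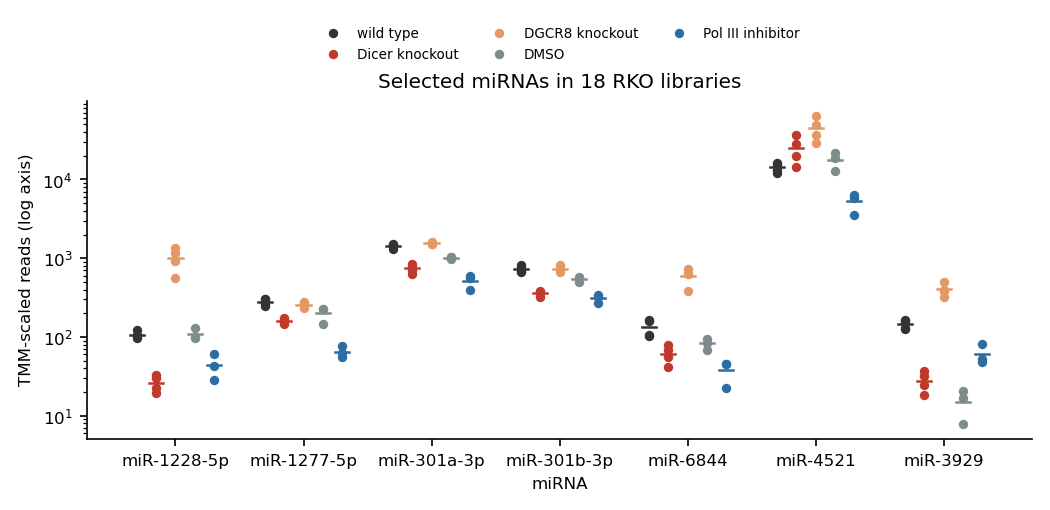
TMM-scaled reads of 7 miRNAs in each RKO library, with group means. On the deposited scale miR-1277-5p, miR-301a-3p and miR-301b-3p are called lower in the DGCR8 knockout than in wild type. There miR-3929 (-0.15) and miR-4521 (-0.015, Dicer knockout -0.20) are not called, and miR-1277-5p lies no higher than in the Dicer knockout.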

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

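In this part the tests of the mir-1829 family against other miRNAs, and the labellings of the inhibitor libraries, were chosen only after the results had been seen. Values of single libraries were compared within each group of 4 RKO libraries by Dixon's ratio, the gap to the nearest library over the range. With 237 tests, about 1 in 20 passes 0.829 by chance, 11.8 in all, and 17 did. In wild type let-7d-3p (ratio 0.933, 711 in replicate 1 against a mean of 404 in the others) and miR-339-5p (0.98, replicate 2) passed. In the Dicer knockout these were let-7a-5p (0.916, replicate 1), miR-190a-5p (0.844, replicate 1), miR-19a-3p (0.88, replicate 1) and miR-1260a (0.874, replicate 3). The others there were miR-3200-5p (0.866, replicate 3), miR-1248 (0.845, replicate 2), miR-339-5p (0.909, replicate 2) and miR-664b-3p (0.876, replicate 2). In the DGCR8 knockout the sum of deposited values was high in replicate 2 (0.941, 9923596 against a mean of 3819632). There let-7d-3p (0.89), miR-21-5p (0.879) and miR-642a-3p (0.886) stood apart in replicate 2. In replicate 1 it was miR-15b-3p (0.948) and miR-941 (0.944), and in replicate 4 miR-1248 (0.935). The direct comparison of ubiquitous with germline Dicer depletion, in which 172 miRNAs were lower, is listed because the groups differed.

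Other splits of the libraries were counted for each comparison. Of 35 splits for the Dicer knockout 1, the real one, gave as many calls (125, highest other 0), the lowest possible share. So it was for the DGCR8 knockout (339, highest other 5) and between the knockouts (360, highest other 18). Other differences following the groups stay open. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and the highest other numbers were 179 and 0 for ubiquitous Dicer depletion (1 split as large), 172 and 0 against germline depletion (1), and 75 and 1 for the inhibitor (1). For germline Dicer depletion they were 16 and 0 (1), and among the 4 splits that part all pairs, the real one included, the others called at most 0. Between the control strains all 10 splits called as many (0, highest other 0 by edgeR, with 0 lower and 0 higher by DESeq2). For RPC-1 depletion 2 splits were as large (2, highest other 78). The split with 78 calls puts TIR1-only replicate 1 with RPC-1 replicates 1 and 2, which points to a structure of the samples: replicate 3 of both groups held more miRNA per spike-in count.

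For the worm intersection 2 of 100 joint splits gave as many miRNAs (2, highest other 62). In 90 of them the Dicer libraries are regrouped, and 0 of these held enough Dicer calls for an intersection as large, so they test only the Dicer calls. That leaves the 10 splits of the RPC-1 libraries, of which 2 gave as many, too few for a share under 0.05. For the RKO intersection 1 of 100 drawn splits, the real one, gave as many (5, highest other 0), but only 6 of the 99 others held enough Dicer calls, again too few. With the knockout libraries in their own groups, 1 of 20 labellings of the inhibitor and DMSO libraries, the real one, gave as many (highest other 4), which cannot give a share under 0.05.

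The mir-1829 family lay lower after RPC-1 depletion. Scaling by the spike-ins is argued against, since within each library the family changed by -1.44 relative to all other tested miRNAs (95% interval -1.88 to -1.0). A missing degron effect in RPC-1 replicate 3 is argued against too, since there the family stood at -3.88 relative to the other miRNAs, below the lowest TIR1-only library (-2.31). Relative to the mir-35 family of oocytes and embryos the change was -0.48 (SE 0.227, 95% interval -1.12 to 0.16), so a loss of germline or embryo RNA cannot be told apart from a need for Pol III, the 3 libraries per group keeping it open. The interval replaced a limit of 2 SE once this value was known, which gives the more cautious reading.

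With the inhibitor, log2 fold changes followed hairpin GC content (Spearman rho 0.25, permutation p = 1.0e-05). This lowest p of 100000 permutations across miRNAs leaves out the spread between libraries. After a linear GC trend was removed, 53 of 76 called miRNAs (69.7%) kept call and direction, among 630 with a GC value. The fall of miR-4521 stayed (-1.63, SE 0.382, limma adjusted p = 0.0152, against -1.76, SE 0.348, before), so a GC trend alone does not account for it. For the lost calls, a GC bias of the libraries cannot be told apart from an inhibitor effect that goes with hairpin GC, since the trend follows the groups.

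On the deposited scale most miRNAs lay lower in the DGCR8 knockout. The fall did not rest on the libraries in which 1 read is worth most (median -1.41 without, -1.53 with). A factor error shared by both replicate 2 libraries would cancel. A loss of miRNAs made by the Microprocessor may lie behind the fall, but the factors' basis is not stated, so a difference in it stays open.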

How the results depend on the processing

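The alternatives on the deposited scale, a mean deposited value of at least 10 or 50, the pseudocounts, the edgeR fit of recovered reads, and leaving out the 4 libraries in which 1 read is worth most or the third library of both RPC-1 groups were added once the tables had been seen. The other alternatives were planned. Over the alternatives, 965 worm values kept direction and side of the threshold, 52 were weaker, 40 stronger and 88 reversed. In RKO these numbers were 2487, 173, 19 and 36. The scaling reverses worm values after Dicer depletion, as listed below. TMM, DESeq2 size factors and total count centre the average miRNA or the total by construction, so a shared fall cannot show there. The RKO main scale centres the same way, and what the deposited factors were set on is not stated. Results on both scales had been seen before the rule fixed in advance settled the main one. The pseudocount of 5 was set once the unit was known and before any fit. The blocked fits' calls had been seen before the pairing check, so the limit of 0.1 was applied as it stood. For the shifts below the cause was not tested, except where fewer libraries or miRNAs in the fit, or the centring, give it.

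Ubiquitous Dicer depletion under TMM gave 47 lower, 28 higher, mir-1829b_3p* at 0.25, mir-1829a_5p at 0.35, mir-1829c_3p* at 0.31, let-7_5p at 0.33 and lin-4_5p at 0.84. Under TMM, germline Dicer depletion gave 2 higher, mir-1_3p at 0.074, let-7_5p at 0.044, mir-80_3p at 0.053 and mir-71_5p at 0.083. Ubiquitous against germline Dicer depletion under TMM gave 29 lower, 23 higher, mir-1829b_3p* at 1.27, mir-1829c_3p* at 1.39, mir-1829c_5p at 0.27, mir-1829b_5p at 0.59, mir-1829a_3p* at 0.70 and mir-1829a_5p at 0.94. It also gave let-7_5p at 0.29 and mir-35_3p at 0.11. RPC-1 depletion under TMM gave 13 lower and 2 higher. Under TMM, the TIR1-only control gave 15 higher and mir-1829a_3p* at 0.080. The worm intersection under TMM held 6 miRNAs. Under DESeq2 size factors, ubiquitous Dicer depletion gave 44 lower, 35 higher, mir-1829b_3p* at 0.32, mir-1829a_5p at 0.43, mir-1829c_3p* at 0.38, let-7_5p at 0.41 and lin-4_5p at 0.91. Germline Dicer depletion under DESeq2 size factors gave 4 higher, mir-1_3p at 0.18, let-7_5p at 0.15, mir-80_3p at 0.16 and mir-71_5p at 0.19. Under DESeq2 size factors, ubiquitous against germline Dicer depletion gave 27 lower, 21 higher, mir-1829b_3p* at 1.24, mir-1829c_3p* at 1.35, mir-1829c_5p at 0.24, mir-1829b_5p at 0.56, mir-1829a_3p* at 0.67 and mir-1829a_5p at 0.92. It also gave let-7_5p at 0.26 and mir-35_3p at 0.092. Under DESeq2 size factors, RPC-1 depletion gave 17 lower and 2 higher. The TIR1-only control under DESeq2 size factors gave 1 lower, 16 higher and mir-1829a_3p* at 0.11. Under DESeq2 size factors, the worm intersection held 6 miRNAs. The inhibitor under DESeq2 size factors gave 22 higher. Under total count, ubiquitous Dicer depletion gave 30 lower, 108 higher, mir-1829b_3p* at 0.82, mir-1829a_3p* at 0.030, mir-1829a_5p at 0.94, mir-1829c_3p* at 0.87, mir-1_3p at 0.45 and let-7_5p at 0.91. It also gave lin-4_5p at 1.42, mir-51_5p at 0.26, mir-62_3p at 0.43 and mir-80_3p at 0.45. Under total count, germline Dicer depletion gave 22 higher, mir-1_3p at 0.46, let-7_5p at 0.41, mir-80_3p at 0.42 and mir-71_5p at 0.45. Ubiquitous against germline Dicer depletion under total count gave 19 lower, 45 higher, mir-1829b_3p* at 1.48, mir-1829c_3p* at 1.6, mir-1829c_5p at 0.48, mir-1829b_5p at 0.80, mir-1829a_3p* at 0.91 and mir-1829a_5p at 1.16. It also gave let-7_5p at 0.50 and mir-35_3p at 0.32. RPC-1 depletion under total count gave 17 lower and 4 higher. Under total count, the TIR1-only control gave 6 lower, 13 higher and mir-1829a_3p* at 0.025. The worm intersection under total count held 6 miRNAs. Under total count, the Dicer knockout gave 30 higher. Under DESeq2 size factors on the spike-ins, RPC-1 depletion gave 5 lower and mir-71_5p at -9.2e-04, and the worm intersection held 5. Germline Dicer depletion with a replicate block gave 44 lower and 1 higher. With a replicate block, RPC-1 depletion gave 20 lower and 4 higher. The TIR1-only control with a replicate block gave 14 lower, 56 higher, mir-1829c_3p* at 0.90, mir-1829b_3p* at 0.89, mir-1829c_5p at 0.20 and mir-1829a_3p* at 0.075. With a replicate block, the intersections gave 20 miRNAs in the worm intersection. By the DESeq2 Wald test, germline Dicer depletion gave 2 higher and RPC-1 depletion 7 lower. The worm intersection then held 7 miRNAs, and the DGCR8 knockout gave miR-301b-3p at -0.0076. The Dicer knockout with no filter gave 14 higher. With no filter, the DGCR8 knockout gave 282 lower, miR-301b-3p at -0.37 and miR-301a-3p at -0.27. DGCR8 against Dicer knockout with no filter gave miR-16-5p at -0.11. With no filter, the inhibitor gave 7 higher. The Dicer knockout with the deposited factors gave 246 lower, 1 higher, miR-361-3p at -0.12, miR-378a-5p at -0.076, miR-7977 at -0.0041, miR-15b-3p at -0.051, miR-664a-3p at -0.25 and miR-4454 at -0.26. It also gave miR-16-5p at -0.48, miR-29a-3p at -0.49 and miR-4521 at -0.20. The DGCR8 knockout with the deposited factors gave 422 lower, 19 higher, miR-301b-3p at -1.59, miR-301a-3p at -1.5, miR-484 at -0.056, miR-4454 at -0.14, miR-1260b at -0.074 and let-7a-5p at -1.09. It also gave miR-16-5p at -1.01, miR-4521 at -0.015 and miR-3929 at -0.15. DGCR8 against Dicer knockout with the deposited factors gave 101 higher, miR-1277-5p at -0.0094, miR-429 at -0.25 and miR-16-5p at -0.53. With the deposited factors, the inhibitor gave 9 lower and 2 higher. The intersections with the deposited factors gave 0 miRNAs in the RKO intersection. In a fit of only the compared groups, germline Dicer depletion gave 1 higher and the inhibitor 4. The DGCR8 knockout then gave miR-301b-3p at -0.023. Without the 4 libraries in which 1 read is worth most, the Dicer knockout gave 34 higher and the inhibitor 9. The DGCR8 knockout then gave miR-301b-3p at -0.27 and miR-301a-3p at -0.13, and against the Dicer knockout miR-16-5p at -0.043. The inhibitor with a mean deposited value of at least 10 gave 15 higher. With at least 50, the DGCR8 knockout gave 100 lower and 62 higher, and against the Dicer knockout 111 and 87.

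Small effects are often missed at this depth and spread together. In simulated data the worm test found 6 of 9 4-fold and 2 of 10 2-fold falls, and the inhibitor test in RKO 34 of 45 and 23 of 44. Leaving 1 library out at a time gave the ranges that follow. For germline Dicer depletion, number lower 9 to 15, mir-1_3p -0.17 to 0.10, mir-80_3p -0.19 to 0.069, let-7_5p -0.16 to 0.022, mir-71_5p -0.12 to 0.014 and number higher 0 to 1. For the TIR1-only control, mir-1829b_5p -0.28 to 0.15, mir-1829c_3p* -0.83 to 0.15, mir-1829b_3p* -0.65 to 0.42, mir-1829a_3p* -0.29 to 0.060 and mir-1829a_5p -0.10 to 0.55. For the intersections, number in the worm intersection 1 to 10. For ubiquitous against germline Dicer depletion, mir-1829c_3p* -0.51 to 0.21. For RPC-1 depletion, number lower 1 to 13, mir-1_3p -0.35 to 0.62, mir-71_5p -0.41 to 0.60 and let-7_5p -0.50 to 0.79. For the Dicer knockout, number higher 25 to 53, miR-21-5p -0.13 to 0.090 and miR-484 -0.14 to 0.0011. For the DGCR8 knockout, miR-301b-3p -0.076 to 0.075. For the inhibitor, number lower 23 to 33, number higher 5 to 22 and miR-1260b -0.43 to 0.042. Without the third library of both RPC-1 groups the number lower was 2.

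Samples with the same replicate number deviated together for germline Dicer depletion, where the blocked values stand beside the results. Elsewhere a pair correlated at 0.1 or less, with ranges of -0.015 to 0.35 (ubiquitous Dicer), 0.051 to 0.36 (ubiquitous against germline), -0.25 to 0.58 (RPC-1), 0.093 to 0.38 (Dicer knockout), -0.59 to 0.25 (DGCR8 knockout), -0.26 to 0.29 (between knockouts) and -0.43 to 0.10 (inhibitor), so the numbers were not taken as pairs. The depths do share a pattern, with the fewest recovered reads in replicate 2 of each RKO group. The TIR1-only and tag controls come from different experiments and were not checked for pairs. Across these comparisons the replicate block gave 192 lower and 0 higher for ubiquitous Dicer depletion, 191 and 0 for ubiquitous against germline, 20 and 4 for RPC-1, 87 and 79 for the Dicer knockout, 186 and 188 for the DGCR8 knockout, 196 and 186 between the knockouts, 46 and 57 for the inhibitor, and 6 in the RKO intersection.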

Other observations

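Among the miRNAs lower with the Pol III inhibitor the median hairpin GC content was 42.2%, against 55.8% for those higher and 52.7% for all tested. Those lower include miR-1277 and miR-374a, at 25.6% and 31.9%, but also miR-1228 and miR-141, at 75.3% and 55.8%.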
